A study of Homo sapiens with 6 samples.

How the data were processed

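Total RNA of A498 cells, an established human renal carcinoma line, was hybridised with Cy3 label to Agilent 1-colour human miRNA arrays, per the labels. The 6 arrays held 3 samples treated with siRNA against SETD2 (siSETD2) and 3 control samples (siNC). Group and replicate numbers were taken from the labels. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

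The deposited values are spot intensities on a linear scale. Per the file headers, Agilent Feature Extraction 10.7.1.1 subtracted the background and detrended each array in space, with no scaling between arrays. The deposited series table of intensities equalled the processed spot signal of the scanner files at all 53144 spots, so it was not a separate alternative. The laboratory protocol before labelling is not given in the sources used here.

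Each array held 53144 spots, of which 2164 were controls. Another 40 spots, of 2 miRNAs, were left out because their names differed between files. The remaining 50940 spots belonged to 5889 probes for 2547 miRNAs, with a median of 20 spots and at most 4 probes per miRNA. The array holds no probe for SETD2 mRNA or for long noncoding RNAs, so neither the depletion of SETD2 nor the long noncoding RNAs planned for testing could be examined.

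Processed intensities were divided by each array's 75th percentile over the 326 probes well above background on all 6 arrays. Values under a floor of 3 times the additive error, at a common -4.15 on the log2 scale, were set to that floor, and log2 was then taken. Spots with outlier marks were left out and the remaining spots of a probe were averaged. A probe was tested if it was well above background on at least 3 of the 6 arrays, which left 513 probes. A miRNA was represented by its probe of highest mean, which gave 292 miRNAs. Among 208 miRNAs with several tested probes the median difference in fold change between probes was 0.09 on the log2 scale, 4 differed by over 1, and 0 had probes past the threshold in opposite directions.

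The siSETD2 and siNC arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided and without a replicate block, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. All fold changes are log2 of siSETD2 over siNC. A miRNA not well above background on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The number of arrays limits the precision. On simulated data for the 513 probes with 200 of them changed, the fit recovered 82% of changes of 1 and 100% of changes of 2 on the log2 scale, with 5 false calls among 187. The simulated values were independent between arrays, with 1 SD per probe for both groups. They held no floor, slide effect or trend on GC content, so these rates do not cover such errors.

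There were 17 miRNA lists (families, genomic clusters, kidney, hypoxia, drug resistance and other cell types), fixed before the data were examined. Another 31 lists of protein-coding genes had no use on this array. Lists with at least 5 tested members were tested with camera, which compares a list with all other tested miRNAs, at a preset correlation of 0.01 and adjusted over the lists tested. Camera with an estimated correlation and fry, which asks whether a list's members move one way on balance, were alternatives. The miRNAs named in the text were set by a rule written before the data were examined: the 10 largest rises and 10 largest falls past the threshold, of at least 1 on the log2 scale and without overlap between the groups, and up to 4 members of smallest adjusted p in each list past its threshold and in the drug-resistance list. These make 50 miRNAs. Any other miRNA named was chosen after its values were seen.

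Probe positions are those of the files in hg19. They were given for 1698 probes and are printed only where the file writes them in ascending order, because the descending ones appear mirrored within the hairpin. Host genes come from a table of GRCh38.p14 used for names and neighbourhood only, without strand or exon structure.

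The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the percentile over all probes, other filters on dim probes, the replicate block, other variance models, the mean of a miRNA's probes, outlier spots kept, and each array left out in turn. Alternatives chosen after seeing the data were no scaling, scaling to Drosophila labelling spike-ins, the slide as a random block, removal of each array's trend on GC content and probe length, fry with the slide as a random block, and the deposited totals per miRNA. The GC trend between probes of 1 miRNA was tested with 100000 random sign changes and a bootstrap of 2000 draws, and other single values with 100000 permutations.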

Results

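The level of mature miRNAs was measured in A498 cells, a human renal carcinoma line, after siRNA against SETD2 (siSETD2, n = 3) and in control samples (siNC, n = 3). SETD2 is the methyltransferase that trimethylates histone H3 on transcribed genes. The comparison addressed which miRNAs differ in level when SETD2 is targeted, in a study of signalling and drug resistance of renal carcinoma. The array carries no SETD2 probe, so the depletion itself is not measured here. The siSETD2 arrays detected 271, 325 and 230 miRNAs well above background and the siNC arrays 308, 274 and 302. Pearson correlations across miRNA probes ranged from 0.952 to 0.982 between siSETD2 arrays, from 0.978 to 0.992 between siNC arrays and from 0.839 to 0.946 between the groups. The median SD of a miRNA was 0.32 on the log2 scale in siSETD2, whose arrays lay on 2 slides, and 0.16 in siNC, whose arrays shared 1.

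In siSETD2 cells miR-21-5p, miR-19b-3p, miR-29b-3p, miR-22-3p and members of the miR-30 and miR-17~92 groups were lower than in siNC cells. A smaller set was higher, led by miR-7110-5p, miR-5787 and miR-642a-3p. Of 292 tested miRNAs, 48 rose and 85 fell (limma, adjusted p under the threshold of 0.05), of which 25 and 50 changed at least 2-fold. The counts past 2-fold were 6 and 14 with normexp correction, 14 and 14 with the trend on GC content and probe length removed, 7 and 83 without scaling, 7 and 74 with spike-in scaling, and 21 and 32 over probes well above background on all arrays. On the level of probes, 94 of 513 rose and 149 fell, against 92 and 96 with normexp correction (median over miRNAs 0.10) and 123 and 129 with median centring. The 3 siSETD2 values lay entirely above or below the 3 siNC values for 189 of the 292 miRNAs, where chance gives 10%. The median fold change was -0.15 on the log2 scale, and the share of rises among the calls was 36.1%. That share moved to 46.4% with median centring (64 rose, 74 fell), to 14.1% without scaling (18 and 110, median -0.49) and to 9.35% with spike-in scaling (10 and 97, median -0.37). The siNC arrays shared 1 slide and the siSETD2 arrays lay on 2 others. With the slide as a random block 20 miRNAs rose and 35 fell, all of them among those called without it. Because the groups share no slide, this block does not separate slide from treatment. Across probes, the difference between the 2 siSETD2 slides had an SD of 0.57 on the log2 scale. The difference between the groups had an SD of 0.87, and that between siSETD2 replicates 1 and 2, on 1 slide, 0.38. These SDs rest on unlike numbers of arrays, so their sizes are not directly comparable. The difference between the siSETD2 slides correlated with the group difference taken without replicate 3 (r = 0.33).

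The largest fall was that of miR-19b-3p, a member of the oncogenic miR-17~92 cluster, from 0.47 ± 0.21 in siNC to -2.79 ± 0.87 in siSETD2 (log2 of scaled intensity, SD, n = 3). It was 9.54-fold lower (log2 fold change -3.25, SE 0.37, adjusted p = 0.000604) and was well above background on 2 of the 3 siSETD2 arrays. Standard errors are those of the log2 fold change. One of its loci lies at chromosome 13, 92003502 to 92003521 (hg19), within the host transcript MIR17HG. miR-29b-3p, known to repress collagen genes, was 6.53-fold lower (SE 0.37). miR-21-5p, one of the brightest miRNAs on the arrays and widely described as an oncogenic miRNA, fell from 5.95 ± 0.20 to 3.88 ± 0.57, 4.20-fold (adjusted p = 0.000703). Its probe lies at chromosome 17, 57918637 to 57918655, within the span of VMP1. miR-22-3p, from the transcript MIR22HG, was 4.12-fold lower (SE 0.25). miR-5100 was 4.05-fold lower, with a spread in siNC (SD 0.96) above that in siSETD2 (SD 0.12). The other large falls were miR-30e-5p, miR-7975, miR-29c-3p, miR-20b-5p and miR-15a-5p, between -1.72 and -1.83. Of these miR-30e-5p and miR-20b-5p were well above background on 1 of 3 siSETD2 arrays.

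The largest rise was that of miR-7110-5p, from -2.39 ± 0.30 to -0.41 ± 0.46, 3.96-fold (SE 0.27, adjusted p = 0.000703). miR-5787 rose 3.64-fold (SE 0.22) and miR-642a-3p 3.33-fold (SE 0.24). miR-7150, miR-6090, miR-4763-3p, miR-328-5p, miR-6891-5p, miR-6749-5p and miR-6794-5p rose by 1.26 to 1.48 on the log2 scale, and miR-6794-5p was well above background on 2 of 3 siNC arrays. By the table of host genes, miR-7110-5p lies within the span of PDIA5, miR-5787 within GNAI2 and miR-642a-3p within GIPR.

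**Figure D1:**
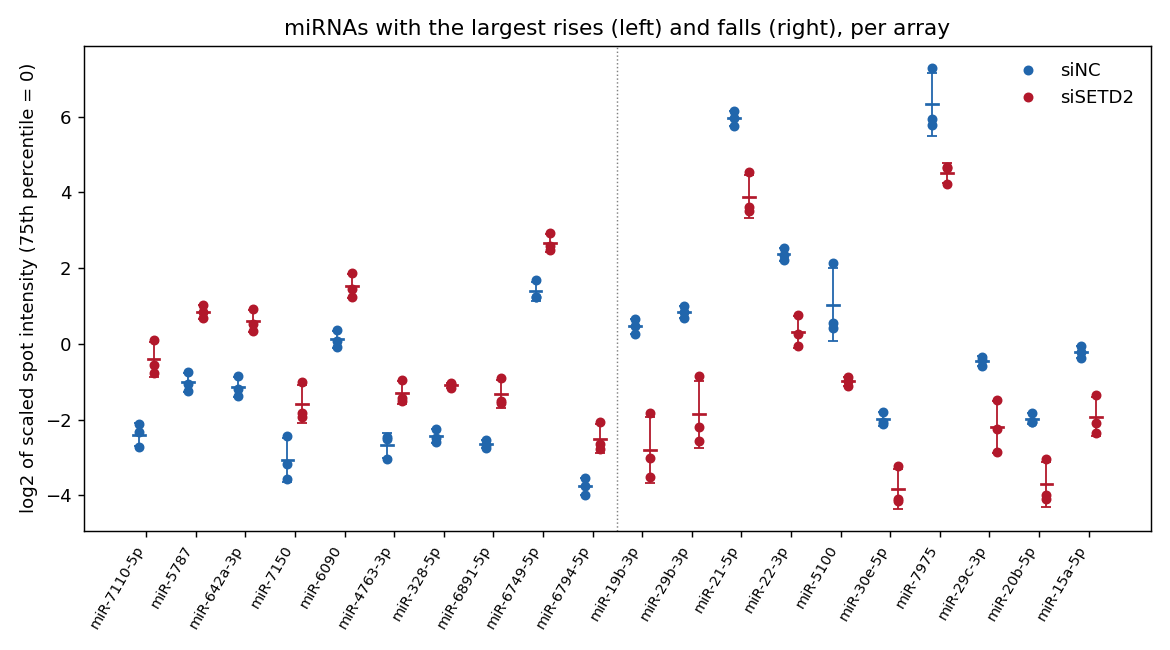
Log2 of scaled spot intensity (y axis, 75th percentile of each array = 0) of the 10 miRNAs with the largest rises and the 10 with the largest falls, with a point per array, the mean as a short line and the SD as a bar (n = 3 per group). Groups without overlap were a condition for the choice of these 20, and miR-19b-3p lies at 0.47 in siNC and -2.79 in siSETD2.

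Every one of the 9 lists with enough tested members moved down against the other miRNAs by camera. Their tested members are all let-7 or numbered below 1000, a class in which 70 of 137 tested miRNAs fell (median -0.67). The 155 numbered 1000 or above had a median of 0.36. The list calls are therefore not separated from the fall of that class as a whole. The kidney and p53-linked lists also share members, among them miR-192-5p and miR-194-5p. With an estimated correlation 0 of the 9 passed (adjusted p = 0.364 to 0.390), the lowest unadjusted p being 0.159, and fry called 9. In the kidney list all 8 tested members fell (median -1.12, camera adjusted p = 0.00263; adjusted p = 0.364 with an estimated correlation). It includes miR-192-5p (-1.63, SE 0.25) and miR-194-5p (-1.43, SE 0.26), which are abundant in renal tubule, miR-10a-5p (-1.16) and miR-30a-5p (-1.25), of which miR-194-5p was well above background on 1 of 3 siSETD2 arrays. All 7 tested members of the miR-30 list fell (median -0.91, adjusted p = 0.0119; adjusted p = 0.364 with an estimated correlation), with miR-30b-5p at -1.41 and miR-30d-5p at -0.91. Both counts were the same adjusted over the list alone. A further tested miR-30 product that the list does not hold, miR-30c-2-3p, did not pass (-0.42, adjusted p = 0.131 by limma).

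Of 10 tested members of the miR-17~92 cluster and its paralogue clusters, which promote proliferation, 7 fell and 3 did not pass (median -1.39, or -1.17 with the 2 members not well above background in siSETD2 at their bounds, adjusted p = 0.00263; adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone 8 fell. miR-20a-5p stood at -1.65 (SE 0.25), and miR-19a-3p, not well above background in siSETD2, was at least 2.03-fold lower. The other, miR-17-3p, was at least 1.21-fold lower, and under normexp correction it turned to 0.02. Of 6 tested p53-linked miRNAs 5 fell, and 5 adjusted over the list alone (median -0.98, adjusted p = 0.0212; adjusted p = 0.364 with an estimated correlation). They include miR-34a-5p (-0.97, SE 0.21), a direct p53 target, and miR-107 (-0.99). With the trend on GC content and probe length removed, the limma calls of both ended, at -0.22 (adjusted p = 0.378) and -0.04 (adjusted p = 0.899). In that setting miR-192-5p and miR-194-5p, also of this list, kept their calls (-0.82 and -0.90). Of 6 hypoxia-linked miRNAs 4 fell, and 5 adjusted over the list alone (median -0.89, adjusted p = 0.0212; adjusted p = 0.364 with an estimated correlation). miR-210-3p, the best-known target of hypoxia-inducible factor, stood at -1.02 (SE 0.21), miR-21-3p at -0.76 and miR-365a-3p at -1.16.

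Of 5 tested members of the miR-23/27/24 clusters 3 fell, also adjusted over the list alone (median -1.04, adjusted p = 0.0294; adjusted p = 0.390 with an estimated correlation). miR-27b-3p stood at -1.43, miR-27a-3p at -1.33 and miR-24-3p at -1.04, while miR-23a-3p had -0.68 (adjusted p = 0.0853). Of 7 members of the miR-99/100 and miR-125 families with miR-10 4 fell, and 5 adjusted over the list alone (median -0.75, adjusted p = 0.0294; adjusted p = 0.364 with an estimated correlation). miR-10b-5p stood at -1.58, miR-125a-5p at -0.75 and miR-100-5p at -0.58. The call of this list ended with normexp (adjusted p = 0.0777), without scaling (0.0619), with the replicate number as a block (0.0590) and with the trend on GC content and probe length removed (0.441). In the miR-200 family, which maintains the epithelial state, 3 of 5 fell, and 4 adjusted over the list alone (median -0.73, or -0.38 with miR-429 and miR-200a-5p at their bounds, adjusted p = 0.0384; adjusted p = 0.364 with an estimated correlation). miR-200a-3p stood at -1.60 and miR-200b-3p at -1.08, and miR-429, not well above background in siSETD2, was at least 1.23-fold lower. miR-200a-5p, also not well above background in siSETD2, did not pass (at least 1.06-fold lower, adjusted p = 0.0677). The call of the miR-200 list ended without siSETD2 replicate 1 (adjusted p = 0.0600), with the replicate block (0.0759), with the trend removed (0.224) and with 4 other scalings or backgrounds: normexp (0.170), the percentile over all probes (0.0535), no scaling (0.0690) and spike-ins (0.0533).

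Of 8 tested members of the let-7 family, which restrains proliferation and RAS, 4 fell, and 7 adjusted over the list alone (median -0.64, adjusted p = 0.0294; adjusted p = 0.390 with an estimated correlation). let-7f-5p stood at -1.09 (SE 0.36), let-7g-5p at -0.97, let-7c-5p at -0.89 and let-7i-5p at -0.65. Under quantile normalization let-7i-5p turned to 0.05 and let-7b-5p, at -0.41 and not past the threshold, to 0.43, and the list's call ended (adjusted p = 0.406). It also ended without scaling (adjusted p = 0.0791) and with the replicate block (0.0759). With the trend on GC content and probe length removed the list reversed, to a median of 0.46 (adjusted p = 0.0230 by camera). That value is at the preset correlation, the only one applied in this setting.

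**Figure D2:**
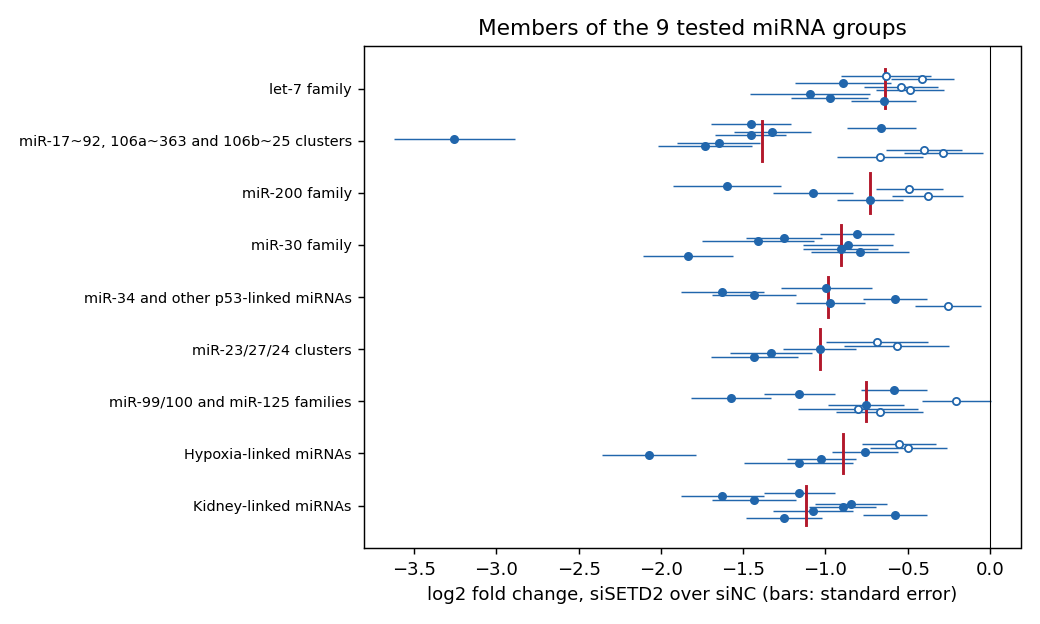
Log2 fold change of siSETD2 over siNC (x axis) of each tested member of the 9 lists, with standard errors as bars, filled points for adjusted p under 0.05, open points for the others and a red line at the list's median. All points lie below 0 at this scaling, and the medians run from -0.64 (let-7) to -1.39 (miR-17~92 and related clusters). Under quantile normalization let-7i-5p and let-7b-5p lie above 0, and under normexp correction miR-17-3p, miR-200a-5p, miR-200b-5p, miR-34b-5p and miR-125a-3p do. With the trend on GC content and probe length removed 19 of the 56 members lie above 0, among them all 8 of let-7. miR-17-3p, miR-19a-3p, miR-200a-5p, miR-429 and miR-215-5p were not well above background in siSETD2, so their points are fitted values and only bounds are known.

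The other lists had under 5 tested members and no list test. In the drug-resistance list miR-21-5p, miR-16-5p (-1.52, SE 0.24) and miR-27a-3p fell, and 3 fell adjusted over the list alone, while miR-15b-5p had -0.18 (adjusted p = 0.496; 0.20 under quantile normalization). With the trend on GC content and probe length removed miR-15b-5p was called higher by limma (0.78, adjusted p = 0.00926). Of 4 tested members of the miR-15/16 family 3 fell, and of 4 of the miR-29 family 3 fell and 1 rose, the latter miR-29b-1-5p at 0.90 (adjusted p = 0.0113). The 2 tested miR-181 members did not pass the test. miR-221-3p, well above background on 2 of 3 siSETD2 arrays, fell (-1.15) and miR-222-3p had -0.39 (adjusted p = 0.213). Of 33 listed miRNAs of the 14q32 cluster 2 were tested, and miR-134-5p rose by 1.12. For each of these lists the counts over the list alone were the same, except that 1 of the 2 members of the 14q32 cluster, miR-494-3p (-0.69), also fell. No member of the 19q13 cluster was tested, nor any of the 19 miRNAs of muscle, liver, neuron and blood. The brightest of the latter, miR-128-3p, had a mean intensity of 10.9.

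The fold changes followed the GC content of the probes. Across the 292 miRNAs, which are not independent replicates, Pearson's r was 0.656 and Spearman's rho 0.700. After removal of each array's trend on GC content and probe length, 27 of the 48 rises and 39 of the 85 falls kept their direction and call. miR-365a-3p was then called in the opposite direction, at 0.53, and so was miR-215-5p, whose siSETD2 values lay near the floor, so that its direction after the removal is not a measured one. Of the 10 largest rises 10 kept their call, of the 10 largest falls 9, and of the 20 largest changes in either direction (3 rises, 17 falls) 18. Those kept include miR-19b-3p at -2.08, miR-21-5p at -0.89 and miR-7110-5p at 1.94, while miR-29c-3p went from -1.74 (SE 0.31) to -0.28 (SE 0.17, adjusted p = 0.242). The miR-17~92 and miR-30 lists stayed lower by camera at its preset correlation (medians -0.60 and -0.54, adjusted p = 0.0230 for both). An estimated correlation, with which neither list passed before the removal (adjusted p = 0.364), was not applied in this setting. All 8 tested members of the reversed let-7 list lay above 0. The calls of the other 6 lists ended, with adjusted p of 0.224 for miR-200 and hypoxia, 0.726 for p53, 0.155 for miR-23/27/24, 0.441 for miR-99/100/125 and 0.164 for kidney.

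**Figure D3:**
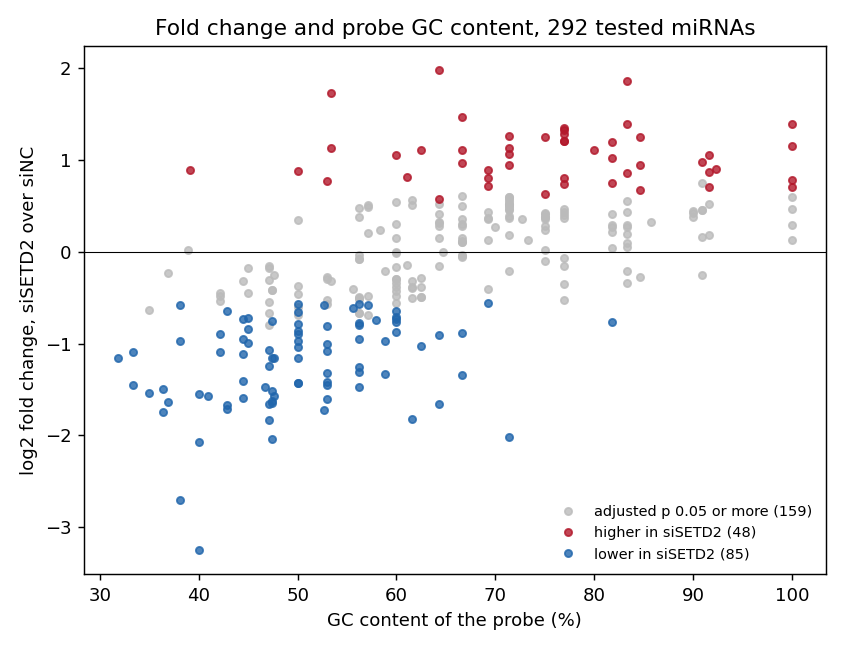
Log2 fold change of siSETD2 over siNC (y axis) against the GC content of the probe in percent (x axis), with a point for each of the 292 tested miRNAs. The 48 miRNAs that rose lie mostly at high GC content and the 85 that fell mostly at low GC content (r = 0.656).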

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

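Of the tests below, those of stringency, of the slide and of a running total were chosen after the results were seen. The others were set before their results.

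The siSETD2 replicate 3 array had a stringency spike-in ratio of 2.71, above the other 5 arrays (1.73 to 1.95), a measure that no comparison uses. It also detected the fewest miRNAs (230).

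AU-rich miRNAs were lower and GC-rich ones higher in siSETD2, with GC slopes of 0.17, 0.06 and 0.30 (log2 per 10 percentage points) on the siSETD2 arrays against -0.19, -0.18 and -0.17 on the siNC arrays. The trend removed from each array was quadratic in GC content and linear in probe length. Its removal also brought the arrays to a common mean over the tested probes, and the median over miRNAs moved from -0.15 to -0.04. A bias of that quadratic and linear form as the whole cause is argued against by 122 of 243 called probes, which kept direction and call afterwards. A sequence bias of another form was not tested. The siSETD2 replicate 3 array alone as the cause is argued against by the 232 called probes that kept both without it. Stringency, as far as the spike-in ratio measures it, did not run with the trend between the groups. For 1 siSETD2 array the ratio lay above the siNC arrays (1.88 to 1.95), and the other 2 lay below them (1.80 and 1.73) with higher GC slopes. Within siSETD2, however, the ratios and the slopes had the same order. Replicate 3 had both the highest ratio (2.71) and the steepest slope (0.30), so a part played by stringency there stays open. Between probes of 1 miRNA, where biology is shared, the slope was 0.101 (95% bootstrap interval 0.029 to 0.185, permutation p = 0.00080) over 130 pairs. Both probes of such a pair were well above background on all arrays. Over all tested probes, dimmer ones included, the slope was 0.355. A part of the trend may therefore come from probe chemistry. How large a part stays open, also because the sets of probes differ. A slide effect cannot be told apart from the group because no slide held both, and a random slide block with a consensus correlation of 0.597 left 90 probes, while SETD2 depletion stays open and RNA quality was not measured.

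The deposited total signal per miRNA, which the comparison does not use, exceeded 1.5 times the signal of the miRNA's own probes on all 6 arrays for 14 miRNAs, and in 391 of 2275 detected totals over the arrays. A first test asked whether the excess equalled the own signal of 1 other miRNA, and within 1% on all arrays that held for 5 of the 14, which left the source undecided. A second test, made after that result, compared each total with that of the preceding detected miRNA in name order plus own probes, and within 1% all 391 matched, against 13 for the following miRNA. A candidate explanation is a running total that was not restarted at the next name. The total of miR-29b-1-5p, for example, was 24.6 to 124 times its own probes and gave -0.74 (adjusted p = 0.0711), where its own probes gave 0.90 (adjusted p = 0.0113), and no biological explanation was tested.

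Of the 10 splits of the 6 arrays into 3 and 3, only the real one, 1 of 10, gave as many calls by limma. It called 243 probes and 133 miRNAs, and the highest other split called 0 of each, with at most 33 probes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached. The real split is also a split by slide, so it does not favour treatment over slide. Every other split mixed the groups, which put any difference between groups or slides into its error.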

How the results depend on the processing

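The settings without scaling, with spike-in scaling, with the slide as a random block, with the GC and length trend removed and with the deposited totals were chosen after seeing the data. For single miRNAs and lists, 1127 values over all settings kept direction and side of the threshold, 151 lost the call, 11 gained one and 17 reversed. Without the filter on dim probes, 1 of 5889 probes passed (300 at an unadjusted p under 0.05 by limma), 0 changed at least 2-fold, and 0 miRNAs were higher and 0 lower. In that setting 4571 probes sat at the floor on every array and entered the variance model. The slide as a random block gave 90 probes, 20 miRNAs higher and 35 lower. Removing the GC and length trend gave 158 probes, 55 of them changed at least 2-fold, 46 miRNAs lower and 3 lists, while camera with an estimated correlation gave 0 lists. Normexp correction left 35 probes changed at least 2-fold. The count of miRNAs higher was 88 with array weights, 18 without scaling and 10 with spike-in scaling, and that of miRNAs lower was 55 over probes well above background on all arrays and 45 with deposited totals. Except where the setting tests fewer probes, the cause was not tested.

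With the GC and length trend removed the direction reversed for let-7g-5p (0.35), let-7i-5p (0.46), let-7c-5p (0.13), let-7f-5p (0.47), miR-19a-3p (0.11), miR-429 (0.14), miR-125a-5p (0.049), miR-100-5p (0.016), miR-365a-3p (0.53), miR-15b-5p (0.78) and the let-7 list (0.46). Of these miR-19a-3p and miR-429 lay at or near the floor in siSETD2, so their values are the removed trend and not a measured rise. Because the removal also brought the arrays to a common mean, signs of values near 0, such as those of miR-125a-5p and miR-100-5p, may depend on that. The direction also reversed for let-7i-5p (0.053) and miR-15b-5p (0.20) under quantile normalization, for miR-15b-5p with array weights (0.018), for miR-200a-5p under normexp correction (0.040), and for miR-194-5p (0.023) and miR-200a-5p (0.18) with the deposited totals. As described above, 391 of 2275 detected totals matched the preceding miRNA's total plus own probes. Values of that setting may therefore carry the signal of another miRNA. miR-15b-5p and miR-200a-5p were not past the threshold at the outset. The cause was not tested. Leaving out each array in turn gave 177 to 271 probes, 96 to 166 changed at least 2-fold, 35 to 59 miRNAs higher, 64 to 88 lower and 8 to 9 lists.

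With the replicate number as a block 251 probes passed, 132 changed at least 2-fold, with 48 miRNAs higher, 86 lower and 6 lists; let-7, miR-200 and miR-99/100/125 lost their call. Same-numbered arrays deviated together with correlations of -0.27, 0.09 and 0.14, and siSETD2 replicate 1 correlated best with siNC replicate 2 (0.36). These values show no pairing by number. With 3 arrays per group, and siSETD2 replicate 3 alone on its slide, they cannot exclude one. The series table equals the scanner signal, no slide held both groups and the arrays share 1 scan day, so these alternatives were not run, nor those for SETD2 and long noncoding RNAs. Few spots are bright: 7.92% to 11.3% were well above background per array, which limits statements on dim miRNAs.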

Other observations

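The tests of a lower share of mature miRNA, and those of the position inside genes and of hairpin arms within the lower-numbered class, were chosen after results were seen, and the others were set before their results.

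The miR-17~92 cluster has 6 tested members, from 1 primary transcript or its paralogue. Log2 fold changes were -0.28 for miR-92a-3p (SE 0.24, adjusted p = 0.319), -1.32 for miR-17-5p (SE 0.23), -1.65 for miR-20a-5p (SE 0.25) and -3.25 for miR-19b-3p (SE 0.37), with probe GC contents of 62.5%, 52.9%, 47.4% and 40.0%. With the trend on GC content and probe length removed they were -0.17 (SE 0.21), -0.84 (SE 0.18), -0.85 (SE 0.21) and -2.08 (SE 0.30). miR-17-3p and miR-19a-3p were not well above background in siSETD2 and have only bounds. Among the 20 hairpins with both arms tested, both arms fell for 6, and for 0 were they called in opposite directions by limma. In the miR-29 family the passenger arm miR-29b-1-5p rose by 0.90 (SE 0.24) while miR-29b-3p fell by 2.71 (SE 0.37), though probes of the latter measure products of 2 loci. miR-92a-3p, miR-17-3p, miR-17-5p and miR-29b-1-5p were chosen after their values were seen.

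miRNAs with older, lower miRBase numbers and newer ones moved apart. Of 137 tested miRNAs of the let-7 family or numbered below 1000, 10 rose and 70 fell (median -0.67, median probe GC content 52.9%), and of 155 numbered 1000 or above 38 rose and 15 fell (median 0.36, median GC content 71.4%). The GC content of the probes differs between these classes, so the difference in number and that in GC content are not separated here.

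For the lower-numbered miRNAs, the variance of the fold changes was 10.3 times their mean squared standard error, and 9.38 times with the trend removed. That argues against a uniform drop in the share of mature miRNA as the only difference between the groups. Such a drop together with a slide effect is not excluded. No slide held both groups, so the standard errors do not measure a slide effect between them. A position inside a protein-coding gene as the whole cause is argued against by the fall of the 53 miRNAs of this class outside such genes: their median was -0.740 (95% bootstrap interval -1.12 to -0.584), 33 of them were called lower by limma, and with the trend removed the median was -0.276 (interval -0.364 to -0.0415). Inside such genes the median was -0.548 and 27 of 64 were called lower. These intervals were drawn over miRNAs, some of which share a transcript, so they do not measure the spread between arrays or slides. Such a position together with a slide effect is not excluded. Whether such a position adds to or lessens the fall stays undecided: with the trend removed, the 64 miRNAs inside had a median 0.151 above that of the 53 outside (95% bootstrap interval -0.10 to 0.29, permutation p = 0.220), and over both classes the difference was 0.101 (permutation p = 0.234), within the bound set in advance against it, which was ill chosen because it pooled the other class with this one. Loss of primary transcripts, a candidate explanation under SETD2 depletion, predicts that the arms of a hairpin move together. Over the 16 hairpins of this class Pearson's r was 0.00534 (95% bootstrap interval -0.395 to 0.375, permutation p = 0.984), and 0.156 with the trend removed (interval -0.320 to 0.542). Both lie below 0.2, the bound set in advance for all hairpins together, but by less than their spread. The test on this class, chosen later, therefore neither supports nor excludes that loss. The r of 0.466 over all 20 hairpins (Spearman's rho 0.456, permutation p = 0.0386) rests on the other 4, numbered above 1000, and says nothing about this class. The squared difference between arms was 5.63 times its squared standard error (interval 3.81 to 7.51) and 2.89 times with the trend removed (1.47 to 4.60). For the 7 hairpins with both arms well above background on all arrays the latter was 2.43 (0.816 to 4.45), so too few bright arms remain to tell. Processing or stability of single miRNAs was not tested and stays open.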
